A study of Mus musculus with 9 samples.

How the data were processed

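Total RNA from N1E-115 cells, a mouse neuroblastoma line, was measured on 9 Affymetrix whole-transcript arrays, 1 array per sample. Per the labels' protocols, cells received 80 nM of a control siRNA or of an siRNA pool against Hmgn5, were kept without serum overnight and were then replated on laminin. Samples carry the times 4 h and 24 h. Per the labels' protocols, the RNA was amplified and converted to sense-strand cDNA, which was fragmented and labelled with biotin. Per the submitters' processing notes, the tools were oligo and RMA, for which no version was given in the sources used here. The deposited values are log2 expression per probe set, as RMA returns them after background correction, quantile normalization and summary over probes. They ranged from 2.13 to 13.9, with array medians between 5.16 and 5.30, and no gene-wise centring was seen. Quantile normalization makes the arrays' distributions alike, so a change shared by most genes would not be visible in these values.

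The table held 41345 probe sets. The platform annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 16010. Of the 23521, 23328 were matched to the RefSeq gene table (GRCm38.p6, used for names only) and no symbol differed. A gene with several probe sets, which applied to 1082 genes, was represented by the probe set with the highest mean over all 9 arrays, which left 22180 genes. Probe sets with several genes or none entered no comparison between groups. Coordinates are not given because the sources used here name no genome build for the array.

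Groups came from the sample titles: control siRNA at 4 h, control siRNA at 24 h and Hmgn5 siRNA at 24 h, with 3 arrays each. These arrays included no Hmgn5 siRNA group at 4 h, so the siRNA effect was estimated at 24 h and the time effect in control cells. Replicate arrays were compared before averaging, and no 2 held the same values. The labels do not say whether the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

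Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values as deposited, all 9 arrays in 1 fit and group means as the model. The fit had 6 residual and 3.55 prior degrees of freedom. Of the 3 contrasts, 2 answer a question of the design: Hmgn5 siRNA minus control siRNA at 24 h, and 24 h minus 4 h in control cells. In the third, Hmgn5 siRNA at 24 h minus control siRNA at 4 h, siRNA and time differ together. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes. The targeted gene was also given an exact two-sided permutation test, which cannot go below 0.1 with 3 arrays against 3.

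The gene lists, 34 in number, were written before the data were examined. They cover chromatin, the cell cycle, neurite and synapse genes, matrix, stress, lipid synthesis and other processes, with markers of glia, fibroblasts, leukocytes and endothelium as other cell types. Of their 1055 genes, 952 were measured by a probe set of 1 gene. Each list was tested with limma's camera at its preset correlation of 0.01 between genes, with adjustment over the 34 lists. Camera with an estimated correlation and limma's fry were alternatives. Members were counted as called over all genes, and again with p-values adjusted over the list alone. A list score per array is the mean over members of the value minus the mean of the 24 h control arrays.

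The rule for named genes was fixed before the data were examined. It takes Hmgn5, and up to 10 rises and 10 falls with the largest log2 difference among called genes whose 2 groups of arrays did not overlap. It adds up to 4 members with the smallest p of each list that passed or is described. Clone and predicted-gene symbols, olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs were left out of the 10s, which passed over 22 rises and 30 falls over time. Genes named outside this rule are said to be so.

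Knockdown and time differences use the same 24 h control arrays with opposite sign. Their covariance across genes was therefore also computed over 6 rotations in which no 24 h control array enters both differences, and in 100 draws of unchanged groups with the measured spread of each gene. The draws were independent between genes. The choices fixed beforehand that were varied one at a time were the replicate number as a block, a fit of only the 2 groups compared, eBayes with a trend and robust prior, array weights, a filter removing the dimmest 33% of genes and cyclic loess. Median centring, every probe set or the mean of a gene's probe sets, a minimum change of 1.5-fold, no empirical Bayes step and leaving out each array were varied as well. Whether the replicate numbers pair the samples was checked before the fits were compared.

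The steps were tested on simulated data made from the real means and spreads, with 200 genes changed. For the knockdown contrast, 59.7% of genes changed by 0.5 log2 units, 97.0% of those changed by 1 and 98.5% of those changed by 2 were called, with 10 false calls among 22180 genes. For the time contrast the shares were 49.3%, 92.5% and 100%, with 9 false calls. With 200 genes changed, the adjusted threshold is easier to reach than with the 3 genes called at the real knockdown. The simulated knockdown shares therefore overstate what the real knockdown contrast could call. A covariance of -0.00999 put into simulated differences was estimated at -0.0102.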

Results

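Hmgn5 is a nucleosome-binding protein that changes chromatin compaction, and the series concerns its part in the growth of neurites from N1E-115 neuroblastoma cells. These cells extend processes when serum is withdrawn and laminin is provided. Expression was measured on 9 arrays, 3 for each of control siRNA at 4 h, control siRNA at 24 h and Hmgn5 siRNA at 24 h. The design gives 2 questions: what lowering Hmgn5 changes at 24 h, and what changes between 4 h and 24 h in control cells. Pearson's r between pairs of arrays lay between 0.978 and 0.995 across probe sets. Control 4 h replicate 2 stood apart, with an array weight of 0.198 where the other arrays had 0.789 to 1.74. Among the pairs without it, r was at least 0.991.

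Hmgn5, the targeted gene, was measured by 1 probe set. Its level was 4.71 ± 0.06 log2 units with control siRNA at 24 h and 3.49 ± 0.04 with Hmgn5 siRNA (mean ± SD, n = 3 each; limma adjusted p = 0.00367). The Hmgn5 signal thus fell by 1.21 on the log2 scale (SE 0.09), to 43.1% of the control signal, or 2.32-fold. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. The 24 h control values exceeded 40.0% to 42.5% of all probe sets on their arrays, and the knockdown values 13.8% to 16.1%. Background at these levels was not estimated, so the share left is that of the array signal, and the fall of the transcript may be larger. In control cells Hmgn5 stood at 4.44 ± 0.19 at 4 h, and its difference of 0.27 between the times did not pass (adjusted p = 0.151).

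Besides Hmgn5, 2 genes changed at knockdown, and both rose. Igfbp5, a secreted binding protein for insulin-like growth factors, rose from 8.14 ± 0.18 to 9.24 ± 0.19 (log2, mean ± SD, n = 3), a difference of 1.09 with SE 0.12 (limma adjusted p = 0.0356). Pltp, a phospholipid transfer protein of lipoproteins, rose from 6.96 ± 0.02 to 7.88 ± 0.06, by 0.92 with SE 0.09 (adjusted p = 0.0296). For both genes all 3 knockdown arrays lay above all 3 control arrays at 24 h. Both genes fell between 4 h and 24 h in control cells, Igfbp5 by 0.50 (adjusted p = 0.0491) and Pltp by 0.85 (adjusted p = 0.00211). No other gene passed. At an unadjusted p under 0.05 there were 1164 genes where chance alone gives 1109, and 12.3% of genes had groups that did not overlap where chance gives 10%. The Igfbp5 call was lost when any 1 of the 9 arrays was left out (adjusted p 0.0506 to 0.335), and the Pltp call when any but control 4 h replicates 1 and 2 was (0.0019 to 0.317 over all 9). The Hmgn5 call was lost without control 24 h replicate 1 or Hmgn5 siRNA replicate 2 or 3 (adjusted p 0.0558, 0.0552 and 0.0506). With the replicate number as a block neither rise passed.

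**Figure D1:**
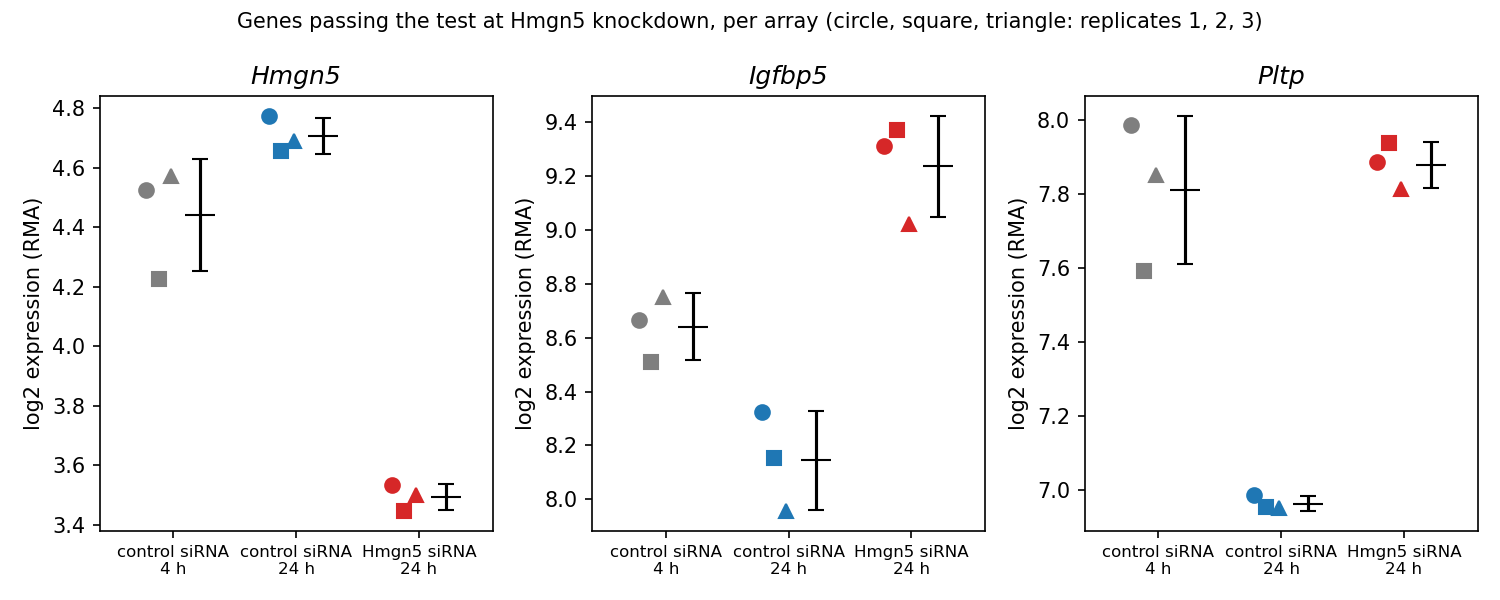
Log2 expression of Hmgn5, Igfbp5 and Pltp on each of the 9 arrays by group, with symbols for the replicate number and bars for the mean and SD of 3 arrays. The knockdown arrays lie below every control for Hmgn5 (3.49 against 4.71 at 24 h) and above every 24 h control for Igfbp5 and Pltp, where Pltp at knockdown (7.88) is near its 4 h level (7.81).

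Growth cone and neurite outgrowth genes did not shift as a group at knockdown. None of the 46 measured passed over all genes or adjusted over the list alone, 21 differences were above 0 and 25 below, and the median was -0.02 (camera adjusted p = 0.587). The members with the smallest p were Klf6, a transcription factor that promotes axon growth (0.34), and Nrn1, a GPI-anchored protein that promotes neurites (-0.18). Next came Dpysl5 (-0.26), a collapsin response mediator protein, and Dclk1 (-0.25), a doublecortin-like kinase. Of 45 axon guidance genes none passed over all genes, and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.367). Adjusted over the list alone, 2 of 44 immediate-early and serum response factor targets and 1 of 34 interferon-stimulated genes were higher. Neither of these lists was called (camera adjusted p = 0.259 and 0.322). Of 12 measured HMG proteins and linker histones only Hmgn5 passed, over all genes and adjusted over the list alone. Values for Hmga2 (-0.19), Hmgb2 (0.15) and the linker histone H1f10 (0.11) did not pass.

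At knockdown 5 lists were called higher at camera's preset correlation, and none kept its call with an estimated one. No member of any of them passed over all genes. The DNA replication and G1/S list had 27 of 28 members above 0 and a median of 0.19 (adjusted p = 3.33e-09, and adjusted p = 0.748 with an estimated correlation). None passed adjusted over the list alone, with Gins1 (0.22) and Mcm4 (0.28) of the replicative helicase, the clamp loader gene Rfc3 (0.27) and the licensing factor gene Cdc6 (0.38) having the smallest p. The G2 and mitosis list had 26 of 30 members above 0, a median of 0.13 and none passing adjusted over the list alone (adjusted p = 0.00142, and adjusted p = 0.798 with an estimated correlation). Its first members were the checkpoint kinase gene Bub1b (0.29), the contractile ring gene Anln (0.35), the kinesin gene Kif23 (0.44) and Cdca8 of the chromosomal passenger complex (0.16). List scores of both moved with single arrays. Hmgn5 siRNA replicate 3 scored 0.42 on the G1/S list against 0.06 and 0.07 on the other knockdown arrays. On the mitosis list, the arrays numbered 3 scored 0.48 with Hmgn5 siRNA and 0.30 with control siRNA, and the other 24 h arrays lay between -0.16 and -0.03. Without Hmgn5 siRNA replicate 3 the mitosis median was -0.04 (adjusted p = 0.571) and the G1/S median 0.08 (adjusted p = 0.012). Without both arrays numbered 3 at 24 h, a choice made after the data had been seen, the medians were 0.10 for mitosis (adjusted p = 1.35e-05) and 0.08 for G1/S (adjusted p = 0.0023). The mitosis list was not called without control 24 h replicate 1 (median 0.06, adjusted p = 0.257) or 2 (0.08, 0.226), and its median was 0.28 without control 24 h replicate 3 and 0.20 and 0.23 without Hmgn5 siRNA replicates 1 and 2.

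The other lists called at knockdown had smaller shifts. The integrated stress response list had 25 of 30 members above 0 and a median of 0.07 (adjusted p = 0.000269, and adjusted p = 0.755 with an estimated correlation). The transcriptional regulators Nupr1 (0.46) and Ddit3 (0.36) passed adjusted over the list alone, and the cystine transporter gene Slc7a11 (0.52) and the phosphatase subunit gene Ppp1r15a (0.37) did not. Of 45 integrin and matrix genes, 25 were above 0, with a median of 0.02 (adjusted p = 0.0221, and adjusted p = 0.624 with an estimated correlation). Itga8 (0.44), an integrin subunit, and Sparc (0.46), a matrix glycoprotein, passed adjusted over the list alone, while the laminin gene Lamc1 (0.27) and the integrin gene Itga4 (-0.23) did not. Ribosome biogenesis and MYC target genes had 28 of 32 members above 0, a median of 0.07 and none passing adjusted over the list alone (adjusted p = 0.00819, and adjusted p = 0.786 with an estimated correlation). Their first members were the nucleolar genes Utp20 (0.16), Dkc1 (0.17) and Ncl (0.10) and the cyclin-dependent kinase gene Cdk4 (0.13). The integrin and ribosome biogenesis lists were not called without control 24 h replicate 2 (adjusted p = 0.086 and 0.11) or Hmgn5 siRNA replicate 3 (0.0707 and 0.0546, with an integrin median of 0.05). Over all alternatives run, the estimated correlation and fry included, the integrin call was lost in 5 and the ribosome biogenesis call in 6. The mesenchymal neuroblastoma list passed with fry (adjusted p = 0.0406) but not with camera at the preset (0.061) or an estimated correlation (0.624). It was led by the annexin gene Anxa2 (0.32), which alone passed over the list. It was followed by Tbx18 (0.24), Notch2 (0.23) and the YAP-related cofactor gene Wwtr1 (0.31). Of 29 sympathetic identity genes, the vesicular monoamine transporter gene Slc18a2 (-0.36) and dopamine beta-hydroxylase, Dbh (-0.42), passed adjusted over the list alone (camera adjusted p = 0.545). Cyb561 (-0.21) and the noradrenaline transporter gene Slc6a2 (-0.22) did not. Marker lists of glia, fibroblasts, leukocytes and endothelium had medians of -0.01, -0.02, -0.05 and 0.00 and were not called.

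**Figure D2:**
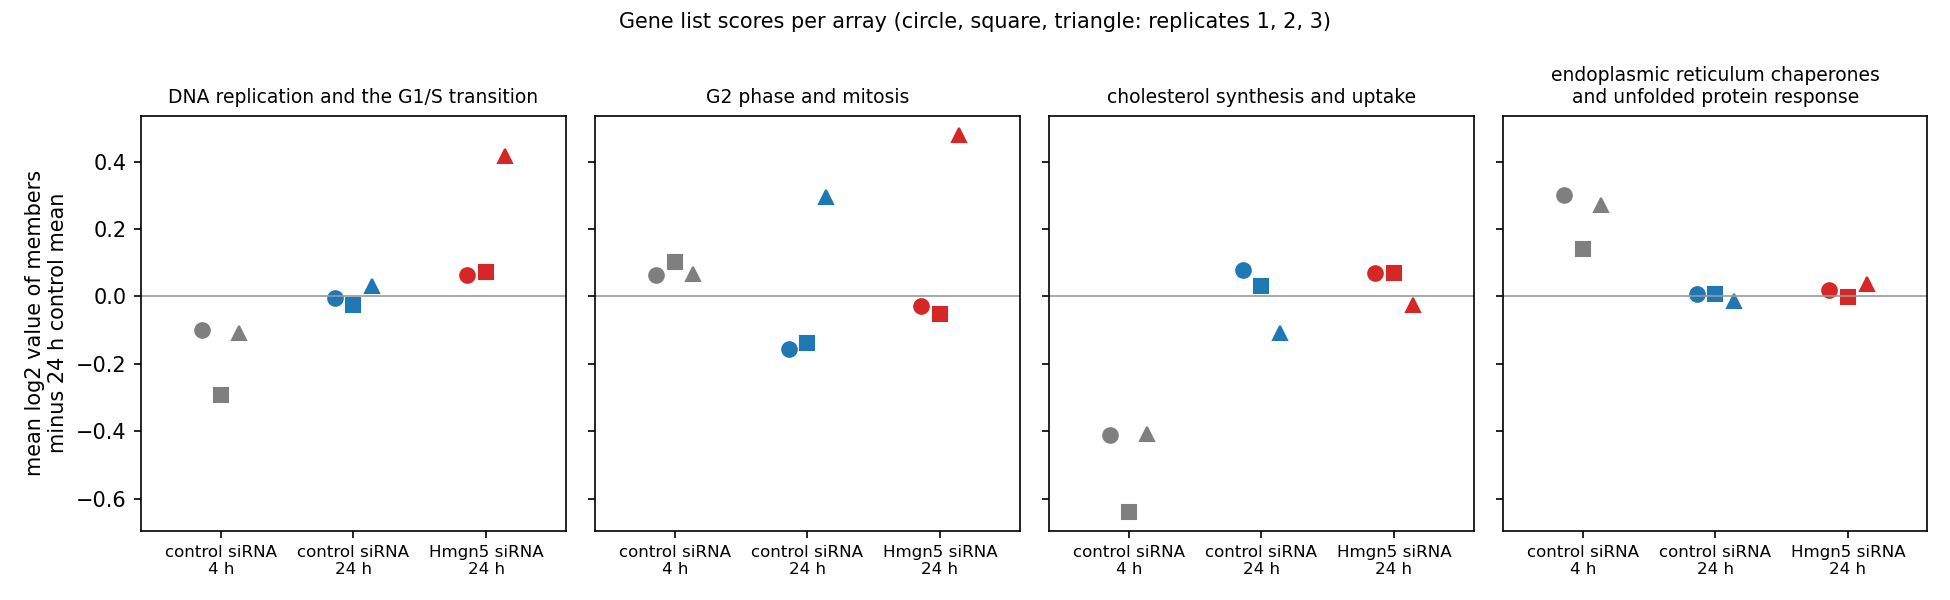
List scores of the 9 arrays, as the mean log2 value of a list's members minus the 24 h control mean, by group and with symbols for the replicate number. On the mitosis panel the arrays numbered 3 at 24 h stand above the others (0.30 and 0.48), and on the cholesterol panel all 4 h arrays lie between -0.64 and -0.41.

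Between 4 h and 24 h in control cells 481 genes rose and 482 fell, 963 of 22180 in all. Among genes kept by the naming rule, the largest rise was that of Gpr6, a G protein-coupled receptor. It rose from 6.38 ± 0.36 to 8.08 ± 0.22 (log2, mean ± SD, n = 3), 3.24-fold with an SE of 0.20 log2 units (adjusted p = 0.00279). Ifit1, an interferon-induced RNA-binding protein, rose by 1.42 (SE 0.32, adjusted p = 0.0406), the chaperone gene Hsph1 by 1.34 (SE 0.10, adjusted p = 0.000447) and the growth arrest cyclin gene Ccng2 by 1.24 (SE 0.13, adjusted p = 0.00209). The largest fall among genes kept by that rule was that of the metallothionein gene Mt2. It fell from 10.02 ± 0.06 to 8.21 ± 0.15, a log2 difference of -1.80 with SE 0.08 (adjusted p = 5.06e-05). The histone deacetylase gene Hdac9 fell by 1.37 (SE 0.10, adjusted p = 0.000436) and Cnn2, an actin-binding calponin, by 1.25 (SE 0.09, adjusted p = 0.000436).

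Other large rises were those of Fam183b (1.26), the angiogenic factor gene Pgf (1.22), the poly-ADP-ribose polymerase gene Parp3 (1.13), the amino acid transporter gene Slc7a7 (1.13), Brinp2 (1.07) and the RING finger gene Rnf112 (1.06). Other large falls were those of Capn6 (-1.18), a calpain-like protein without protease activity, the secreted phospholipase gene Pla2g2e (-1.16) and the iron-siderophore binder Lcn2 (-1.13). Gnpnat1 (-1.10) of the hexosamine pathway, Mamdc2 (-1.06), the cytochrome c oxidase subunit gene Cox7a1 (-1.05) and the RNA export factor gene Nxf7 (-1.05) fell as well. The Ifit1 call was lost with any 1 array left out except Hmgn5 siRNA replicate 3 (adjusted p up to 0.114), and the Rnf112 call with any except control 4 h replicates 1 and 2 (up to 0.128). Changes were mostly below 1.5-fold, with 152 rises and 81 falls above it. With each array centred on its median there were 477 rises and 309 falls. Leaving out 1 array of the 24 h controls gave 178 to 230 rises and 132 to 177 falls, leaving out control 4 h replicate 3 gave 316 and 272, and leaving out Hmgn5 siRNA replicate 1 or 2 gave 316 and 308 or 329 and 317. Without control 4 h replicate 2 there were 586 rises and 652 falls, and 818 of the 963 calls were among them.

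Lists tested over time gave 11 called higher and 4 called lower at camera's preset correlation. None of the 15 passed with an estimated correlation, and fry called 12 lists. Cholesterol synthesis and uptake shifted most, with all 19 measured members above 0. Of these 11 rose, 18 passed adjusted over the list alone, and the median was 0.49 (adjusted p = 3.96e-16, and adjusted p = 0.175 with an estimated correlation). Rises included the sterol reductase gene Tm7sf2 (0.62), the squalene synthase gene Fdft1 (0.49), the methylsterol oxidase gene Msmo1 (0.49) and the sterol dehydrogenase gene Nsdhl (0.47). Of 16 fatty acid synthesis genes 5 rose, and adjusted over the list alone 6 were higher and 1 lower (median 0.20, adjusted p = 0.000764, and adjusted p = 0.474 with an estimated correlation). They included the lipogenic transcription factor gene Srebf1 (0.50), the acetyl-CoA synthetase gene Acss2 (0.40), the phosphatidate phosphatase gene Lpin1 (0.61) and the elongase gene Elovl6 (0.40). The Srebf1 call was lost without control 24 h replicate 1 or 2 (adjusted p up to 0.0723), and the Acss2 call without these or control 4 h replicate 1 (up to 0.0784). The Lpin1 call was lost with any 1 array left out except control 4 h replicate 1 and Hmgn5 siRNA replicate 3 (up to 0.124), and the Elovl6 call with any except control 4 h replicates 1 and 2 (up to 0.128). On the cholesterol list control 4 h replicate 2 scored -0.64 and the other 4 h arrays both -0.41, and on the fatty acid list it scored -0.30 against -0.14 and -0.16.

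Chaperone lists of the cytosol and the endoplasmic reticulum were called in opposite directions over time at the preset correlation. Of 18 cytosolic heat shock genes 8 rose, the same number as adjusted over the list alone, with a median of 0.29 (adjusted p = 1.12e-07, and adjusted p = 0.0503 with an estimated correlation). Besides Hsph1, they included the Hsp110 relative Hspa4l (0.56) and the Hsp90 co-chaperone genes Ahsa1 (0.61) and Stip1 (0.32), whose call was lost without any 1 of the 24 h control arrays (adjusted p up to 0.0591). Of 24 endoplasmic reticulum chaperone and unfolded protein response genes 8 fell, 13 adjusted over the list alone, with a median of -0.24 (adjusted p = 1.27e-10, and adjusted p = 0.212 with an estimated correlation). Falls included the co-chaperone gene Dnajb9 (-0.66), the secreted factor gene Manf (-0.55), the chaperone gene Hspa5 (-0.49) and Herpud1 (-0.48), which acts in degradation at the endoplasmic reticulum. Control 4 h replicate 2 scored 0.14 on this list against 0.30 and 0.27 on the other 4 h arrays. In the integrated stress response list 5 of 30 genes fell and 1 rose, 8 and 1 adjusted over the list alone (median -0.08, adjusted p = 0.00171, and adjusted p = 0.551 with an estimated correlation). Nupr1 (-0.77), Ddit3 (-0.58), the folate enzyme gene Mthfd2 (-0.26) and the amino acid transporter gene Slc7a1 (-0.24) fell. The Mthfd2 and Slc7a1 calls were lost with any 1 array left out except control 4 h replicate 2 (both adjusted p up to 0.133). On the integrated stress list control 4 h replicate 2 scored -0.08 against 0.21 on both other 4 h arrays. Without it the median was -0.17 (adjusted p = 8.07e-09), and the list was not called without control 4 h replicate 1 (-0.03, adjusted p = 0.0849) or 3 (-0.05, 0.0661).

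Lists of neurite outgrowth, microtubule, synaptic and sympathetic genes were called higher, while those of neuronal markers (camera adjusted p = 0.116, fry 0.00516) and of axon guidance genes (camera adjusted p = 0.213) were not called by camera. Of 46 growth cone and neurite outgrowth genes 5 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 0.13 (adjusted p = 0.00121, and adjusted p = 0.22 with an estimated correlation). Stmn4, a stathmin that regulates microtubules, rose by 1.03, the adhesion molecule gene Cntn2 by 0.60 and Klf6 by 0.42. Dcx, the microtubule-associated doublecortin of migrating neurons, fell by 0.99. A second probe set of Stmn4 gave 0.23. The Klf6 call was lost without any 1 of the 24 h control arrays (adjusted p up to 0.063) and the Cntn2 call without control 24 h replicate 1 or 2 (up to 0.072). Of 30 microtubule proteins and motors 3 rose, 4 adjusted over the list alone (median 0.15, adjusted p = 0.000764, and adjusted p = 0.267 with an estimated correlation). They were the dendritic protein gene Map2 (0.62), the tubulin gene Tubb2b (0.64) and the kinesin gene Kif1a (0.55), while Mapre2 (0.35) did not pass. The Tubb2b call was lost with any 1 array left out except those at 4 h (adjusted p up to 0.124), and the Kif1a call with any except control 4 h replicate 1 and Hmgn5 siRNA replicates 1 and 3 (up to 0.112). On the neurite list control 4 h replicate 2 scored -0.22 against -0.10 and -0.08 on the other 4 h arrays, and on the microtubule list -0.29 against -0.09 and -0.10. Without it the medians were 0.07 (adjusted p = 0.0076) and 0.09 (adjusted p = 0.00691).

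Of 45 synaptic and ion channel genes 6 rose and 1 fell, 7 and 2 adjusted over the list alone (median 0.11, adjusted p = 0.0025, and adjusted p = 0.218 with an estimated correlation). The sodium channel gene Scn3a (0.51) and the synaptotagmin genes Syt1 (0.36) and Syt11 (0.30) rose, and the synaptotagmin gene Syt4 (-0.50) fell. Calls were lost without control 4 h replicate 3 or control 24 h replicate 1 for all 3 synaptotagmins, without control 24 h replicate 3 for Syt1 and Syt11, without control 24 h replicate 2 for Syt4 and Syt11, and without control 4 h replicate 1 for Syt11 (adjusted p up to 0.0697 for Syt1, 0.0727 for Syt4 and 0.0863 for Syt11). In the sympathetic identity list 4 of 29 genes rose, and adjusted over the list alone 5 were higher and 1 lower (median 0.06, adjusted p = 0.00753, and adjusted p = 0.412 with an estimated correlation). They were the catecholamine genes Dbh (0.80) and Th (0.53), the vesicular transporter gene Slc18a1 (0.80) and the neurotrophin receptor gene Ngfr (0.65). The Th and Ngfr calls were lost without any 1 of the 24 h control arrays (adjusted p up to 0.0774 and 0.0712). On the sympathetic list control 4 h replicate 2 scored -0.28 against -0.09 and -0.10, and without it the list was not called (adjusted p = 0.0801). The median was 0.11 without control 4 h replicate 1 or 3 and 0.12 without control 24 h replicate 3.

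The interferon and growth arrest lists were called higher over time at the preset correlation. Of 34 interferon-stimulated genes 5 rose, 7 adjusted over the list alone (median 0.14, adjusted p = 0.000203, and adjusted p = 0.0503 with an estimated correlation). Stat2 (1.01), a transducer of interferon signalling, Oasl2 (0.80) and Ifi35 (0.38) rose with Ifit1, and a second probe set of Ifi35 gave -0.06. The Ifi35 call was lost without control 24 h replicate 1 or 2 (adjusted p up to 0.059), and the Oasl2 call with any 1 array left out except control 4 h replicate 2, control 24 h replicate 2 and Hmgn5 siRNA replicate 3 (up to 0.0802). Among 27 FoxO target and growth arrest genes Ccng2 (1.24), the insulin receptor gene Insr (0.34) and the sestrin gene Sesn3 (0.27) rose, and Pink1 (0.76) did not pass. The Insr call was lost without control 24 h replicate 1 (adjusted p = 0.0563), and the Sesn3 call with any 1 array left out except control 4 h replicates 1 and 2 (up to 0.137). The score of control 4 h replicate 2 on this list was -0.32, against -0.15 and -0.13. Adjusted over the list alone 4 were higher (median 0.14, adjusted p = 0.000613, and adjusted p = 0.218 with an estimated correlation). In the DNA replication and G1/S list E2f1 (0.39), a transcription factor of S phase entry, rose, and its call was lost with any 1 array left out except control 4 h replicate 1 (adjusted p up to 0.155). The other genes did not pass, among them Gins2 (0.33), Slbp (0.25) and Tk1 (0.56). None passed adjusted over the list alone (median 0.19, adjusted p = 0.00284, and adjusted p = 0.556 with an estimated correlation). Control 4 h replicate 2 scored -0.29 on that list against -0.10 and -0.11 on the other 4 h arrays, and without it the list was not called (median 0.11, adjusted p = 0.076). The oxidative phosphorylation list was called higher with a median of 0.06 and 0 of 39 members passing over all genes or adjusted over the list alone (adjusted p = 0.0333, and adjusted p = 0.267 with an estimated correlation). It was not called without control 4 h replicate 1 (adjusted p = 0.0849) or 2 (0.0518) or without control 24 h replicate 1 (0.171). Its members with the smallest p were Uqcrfs1 (0.31), Cox7c (-0.23), Sdhd (0.13) and Cox5a (0.15).

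Besides the endoplasmic reticulum and integrated stress lists, the ribosome biogenesis and chromatin lists were called lower over time at the preset correlation. Of 32 ribosome biogenesis and MYC target genes 3 fell, 7 adjusted over the list alone, with a median of -0.13 (adjusted p = 1.97e-05, and adjusted p = 0.412 with an estimated correlation). Utp20 (-0.43) of the small subunit processome, the nucleolar GTPase gene Gnl3 (-0.39) and the helicase gene Ddx21 (-0.32) fell, and the polymerase subunit gene Polr1b (-0.31) did not pass. A second probe set of Ddx21 gave -0.14, and the Ddx21 call was lost with any 1 array left out except control 4 h replicate 2 and Hmgn5 siRNA replicate 3 (adjusted p up to 0.116). The score of control 4 h replicate 2 on this list was -0.02, within the 24 h control arrays (-0.02 to 0.03), against 0.26 and 0.21 on the other 4 h arrays. The median was -0.23 without it (adjusted p = 4.29e-14) and -0.06 without control 4 h replicate 1 (adjusted p = 0.00699). Of 37 nucleosome remodelling and histone-modifying enzymes 4 fell, and adjusted over the list alone 7 were lower and 1 higher (median -0.05, adjusted p = 0.0025, and adjusted p = 0.337 with an estimated correlation). These were the deacetylase gene Sirt1 (-0.43), the remodelling ATPase genes Ino80 (-0.48) and Chd1 (-0.40) and the SWI/SNF subunit gene Smarcd1 (-0.28), whose second probe set gave -0.03. The Smarcd1 call was lost with any 1 array left out (adjusted p 0.0643 to 0.152), and the Chd1 call with any except Hmgn5 siRNA replicate 3 (up to 0.113). The chromatin median was -0.03 without control 4 h replicate 1 or control 24 h replicate 3. The marker lists of glia, fibroblasts, leukocytes and endothelium had medians of 0.04, 0.04, 0.00 and 0.01 and were not called.

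**Figure D3:**
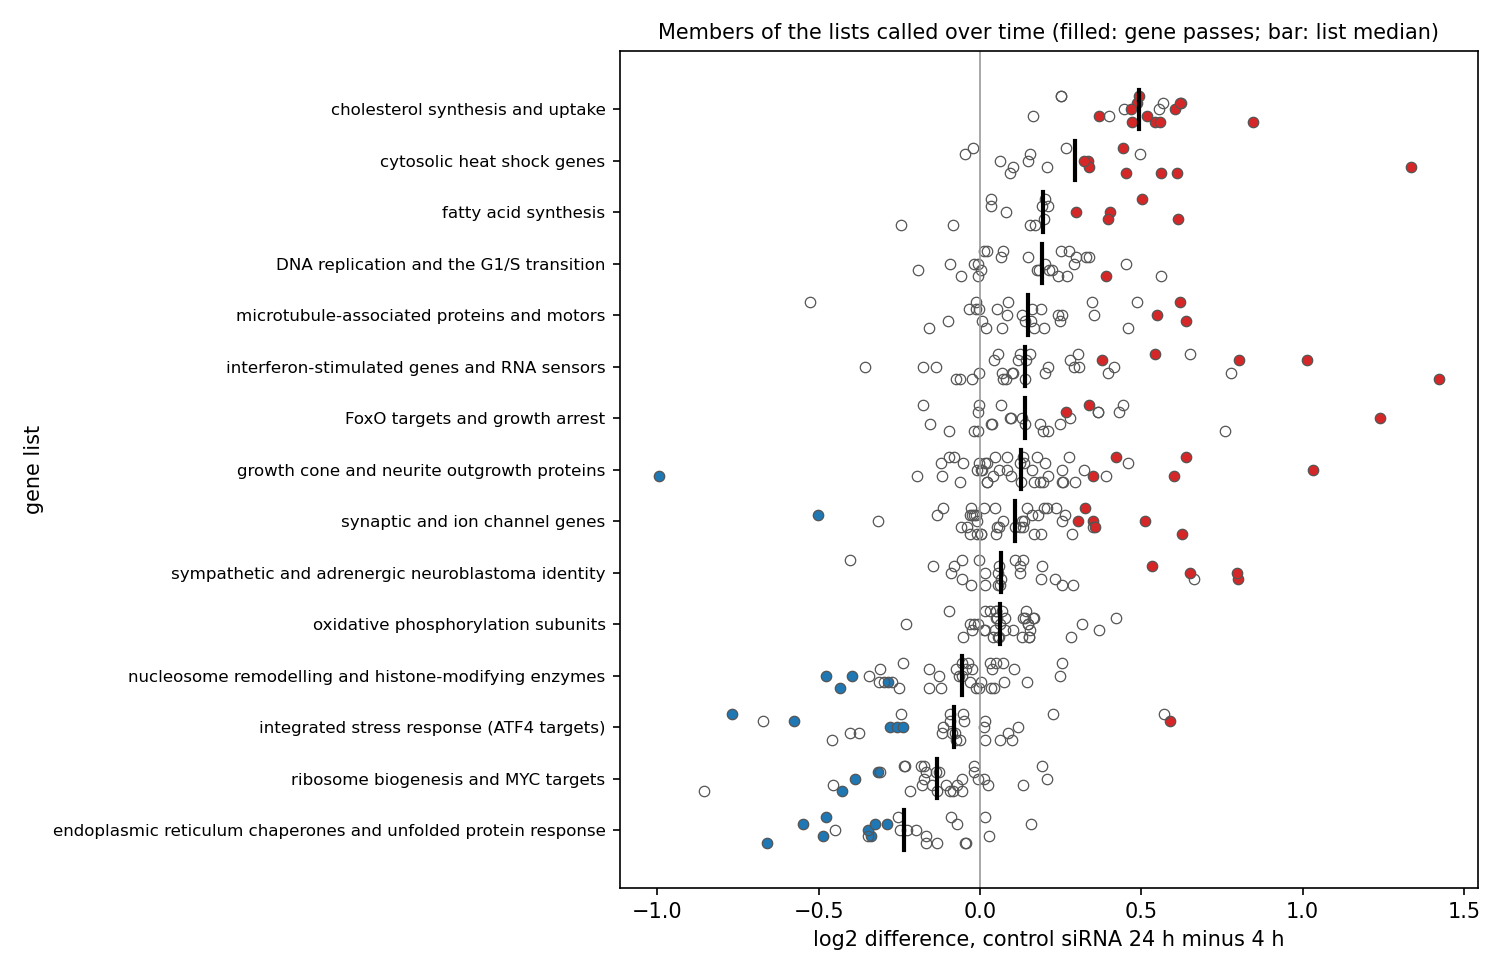
Log2 difference between 24 h and 4 h in control cells for each member of the 15 lists called at camera's preset correlation, with filled points for genes that passed over all genes and a bar at the list median. Medians run from -0.24 for endoplasmic reticulum chaperones to 0.49 for cholesterol synthesis.

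Set against control cells at 4 h, cells with Hmgn5 siRNA at 24 h had 338 genes higher and 231 lower, a comparison in which siRNA and time differ together. Hsph1 differed by 1.32, Gpr6 by 1.43, Mt2 by -2.19 and Hspa5 by -0.45, each passing and in the direction of the time difference. Igfbp5 did not follow that direction and was 0.59 above its 4 h level (adjusted p = 0.0335), and Pltp (0.07) and Capn6 (-0.16) did not pass. The heat shock list (median 0.33) and the interferon list (median 0.17) were called higher with an estimated correlation as well, both at adjusted p = 0.0189. The calls shared with the time comparison were 265 higher and 179 lower. In simulated groups without change against the same 4 h arrays, as many genes as were called, taken by smallest p in each direction, shared 182 and 140 on average over 100 draws, at most 200 and 157. With median centring the counts were 375 higher and 148 lower, and without control 4 h replicate 2 they were 445 and 339. Leaving out Hmgn5 siRNA replicate 1, 2 or 3 gave 95 and 80, 105 and 60, or 147 and 74. Leaving out control 4 h replicate 3 gave 209 and 114, control 24 h replicate 1 or 2 gave 212 and 126 or 218 and 131, and control 4 h replicate 1 gave 249 and 152.

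Knockdown and time differences were opposed in sign across genes, as differences that share the 24 h controls with opposite sign are. Both genes that rose at knockdown, Igfbp5 and Pltp, were among the 482 that fell over time. In simulated groups without change that share the 24 h controls, the 2 rises and 482 falls with the smallest p had 1.24 genes in common on average, and both in 33 of 100 draws. The integrated stress and ribosome biogenesis lists were called higher at knockdown and lower over time, while the G1/S list was called higher in both. The shared controls favour opposed calls of lists and of their members too, and no simulation was made for lists. Across the 22180 genes, which are not independent replicates, Pearson's r was -0.395, against a mean of -0.41 for simulated unchanged groups. The covariance was -0.00837 against -0.00492 in the simulation, a difference of -0.00345. Over the 6 rotations in which no 24 h control array was shared, all covariances were negative, from -0.00469 to -0.00198, with r between -0.187 and -0.0715. Time genes were also chosen without 1 of the 24 h control arrays, which then alone served as the control of the knockdown. The median knockdown difference of these genes, signed by their time change, was -0.08, -0.07 and -0.08 over 355, 310 and 407 genes, and 68.3% to 74.4% of them were opposed. No simulated or relabelled share was computed for this measure. The values share the same knockdown and 4 h arrays, so they are not separate tests.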

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

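The tests of the slope of 1 array, of the covariance without a shared array, of splits along the time difference and of the cell cycle lists were chosen as tests of these explanations after the results were seen. Among 17824 probe sets with several genes or no gene symbol, which the comparisons leave out, 2 rose and 3 fell between 4 h and 24 h (limma, adjusted over these probe sets), a signal in data outside the comparisons. The 2 that rose were 17301207, annotated to several genes, by 0.91, and 17461341 by 0.66. The largest fall among these probe sets was that of 17285851, annotated to several H2B histone genes, by a log2 difference of -1.81. It was followed by 17366768 (-1.07) and 17200437 (-0.97), neither with a gene symbol. These probe sets were named after their values were seen. At knockdown none of them passed, with 639 at an unadjusted p under 0.05 where chance gives 891.2.

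Control 4 h replicate 2 lay far from the other arrays, at -35.0 on the first principal component where the others ran from -6.42 to 10.2. Its deviation from the other arrays had a slope of -0.025 on gene level, outside the range of -0.0107 to 0.00992 of the other 8, so that its highly expressed genes read low (median -0.05 among the most highly expressed genes). A compressed signal from this sample's RNA or labelling is consistent with that slope. On 1238 time genes chosen without it, it lay at 101% of the distance from the 24 h controls to the other 4 h arrays. Left-out 24 h control arrays lay at 7.17% to 8.90%, and the other 4 h arrays, left out in turn, at 77.3% and 84.3%. On time genes this argues against a 24 h sample under a 4 h label. On the second principal component, however, control 4 h replicate 2 lay at -10.7. There the 24 h arrays ran from -6.71 to 0.737, and the other 4 h arrays lay at 16.6 and 14.8. No biological explanation was tested, since the labels give no difference between the 4 h samples.

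Knockdown differences ran against time differences. The shared 24 h controls as the whole cause would give a covariance near 0 without a shared array, and it was -0.00347, below the -0.000443 that was the lowest of 100 simulated draws. The draws treat genes as independent, whereas genes moved together within groups, with an estimated correlation of 0.844 in the mitosis list. The value thus exceeds what independent noise gives, but it does not by itself exclude the shared controls as the whole cause. Variation among the 24 h arrays that does not follow the siRNA stays open. For its test, the time difference was the mean of all 6 arrays at 24 h, knockdown included, minus the 4 h mean. Its values are therefore not on the same measure as -0.00347. Of the 10 splits of these 6 arrays, 3 gave an absolute covariance as large, the real one included, at most 0.0029 against 0.00209 for the real split. A slower course with less Hmgn5 may be proposed, but these arrays do not separate it from such variation. The arrays included no Hmgn5 siRNA group at 4 h.

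The G1/S and mitosis lists were called higher at knockdown at a preset correlation between genes, and neither was with an estimated one (adjusted p = 0.748 and 0.798). The DNA replication and G1/S list was still called without Hmgn5 siRNA replicate 3 (adjusted p = 0.012) and without both arrays numbered 3 at 24 h (0.0023), although the median went from 0.19 to 0.08. Those calls use the preset correlation of 0.01, where the estimated one for this list was 0.461. They therefore do not decide whether Hmgn5 siRNA replicate 3 is the whole cause. For the mitosis list that stays open as well. It was not called without Hmgn5 siRNA replicate 3 (adjusted p = 0.571), which leaves the high control array numbered 3 in place, but was called without both (1.35e-05). With the replicate number as a block the mitosis list was called too (adjusted p = 5.22e-05 at the preset correlation). Differences in cycling between arrays of 1 group stay open for both. Members of these lists moved together within groups, with estimated correlations of 0.461 for G1/S and 0.844 for mitosis. Whether this gave the calls is not decided, because every list called at knockdown lost its call with the estimated correlation. That includes the integrin list, where it was 0.0169. A biological effect of the siRNA on cycling stays untested, and cell cycle phase was not analysed here.

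Other splits of the same 6 arrays, of which there are 10 per comparison, are too few for a share under 0.05. The real knockdown split called 3 genes, the time split 963 and the split of knockdown at 24 h from control at 4 h 569, and no other split called any, so 1 of 10 reached each count. For lists at knockdown, 4 of 10 splits called at least the real 5, the real one included, and the highest other called 7. That split put both arrays numbered 3 on the same side. Over time 1 of 10 splits reached the real 15 lists, and the highest other called 11.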

How the results depend on the processing

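Knockdown calls depended on the setting. With the replicate number as a block 0 genes rose and 1 fell, and after the data had been seen control 4 h replicate 2 was also taken out of that block fit, which gave 1 rise, that of Pltp. The numbers were not taken to pair the samples in the main fit, but the values lean towards pairing without settling it. Between 24 h arrays of the same number, deviations from the group means had r of 0.184, 0.0891 and 0.285, against at most 0.081 for other numbers. Between 4 h and 24 h arrays of the same number r was at most 0.0921, against at most 0.0231 for other numbers. Arrays of the same number were more alike in every case except replicate 1 of the 4 h controls and Hmgn5 siRNA (0.00851 against 0.0231). A fit of only the 2 groups gave 1 rise (Pltp), eBayes with a trend and robust prior 4 (with Capn6 and Nrp2) and array weights 6 (with Prkg1 and Sparc as well). Without dim genes 0 falls were left, because the filter took Hmgn5 out. Without empirical Bayes 0 genes rose and 0 fell, and Hmgn5, at -1.21, had adjusted p = 0.106. Leaving out 1 array gave 0 to 1 rises and 0 to 2 falls. The second fall, without control 24 h replicate 3, was that of Cdkl1 (-0.77), a gene outside the naming rule. With 1 array left out the Hmgn5 difference lay between -1.24 and -1.18, with values of -1.18, -1.19 and -1.22 where its call was lost. Without both arrays numbered 3 at 24 h, a choice made after the data had been seen, 0 genes rose, 0 fell and Hmgn5 differed by -1.23 (adjusted p = 0.2).

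The number of time calls depended on the setting. The rises and falls were 161 and 119 in a fit of only the 2 groups, 807 and 878 with array weights, 228 and 252 without empirical Bayes and 152 and 81 with a minimum of 1.5-fold. Median centring gave 477 and 309, so that 60.7% of calls were higher where it had been 49.9%. Leaving out 1 array gave 178 to 586 rises and 132 to 652 falls, and leaving out both arrays numbered 3 at 24 h gave 149 and 117. Of the 963 calls, 273 were shared with the fit of only the 2 groups. Of 85 calls of named genes over time, 44 held in every setting apart from the minimum of 1.5-fold.

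Cells with Hmgn5 siRNA at 24 h against control cells at 4 h had 75 genes higher and 38 lower in a fit of only the 2 groups, 697 and 529 with array weights, 136 and 119 without empirical Bayes and 98 and 47 with a minimum of 1.5-fold. Median centring gave 375 and 148, or 71.7% higher against 59.4%. Leaving out 1 array gave 95 to 445 higher and 60 to 339 lower, and leaving out both arrays numbered 3 gave 71 and 43.

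Gene list calls depended on whether camera used its preset correlation or an estimated one. The size of the correlation is not the whole reason. The interferon list over time had an estimated correlation of -0.007, below the preset 0.01, and still lost its call (camera adjusted p = 0.0503). The unadjusted camera p of this list went from 2.99e-05 to 0.00296. A call lost with an estimated correlation therefore does not by itself show that the members of a list moved together. With an estimated correlation 0 lists were called higher at knockdown, and 0 higher and 0 lower over time. With fry 1 list was called higher at knockdown and 2 were called lower over time. Without dim genes 1 list was called lower at knockdown. Leaving out 1 array gave 2 to 6 lists higher and 0 to 1 lower at knockdown, with 2 without control 24 h replicate 2 and 3 without Hmgn5 siRNA replicate 3. Over time it gave 8 to 12 higher and 3 to 5 lower. The G2 and mitosis median changed sign without Hmgn5 siRNA replicate 3, and ranged from -0.035 there to 0.28 without control 24 h replicate 3. Without both of these arrays it was 0.10 and the list was called (adjusted p = 1.35e-05). Of the 15 lists called over time 11, and of the 5 called at knockdown 2, the G1/S and integrated stress lists, held with the replicate block, without dim genes, with cyclic loess, with median centring and with any 1 array left out. Lists were not tested in fits of only the 2 groups, with array weights, with trend and robust, without empirical Bayes, with a minimum of 1.5-fold or with other choices of probe sets. The covariance of knockdown and time differences without a shared array was -0.00528 without dim genes and lay between -0.00419 and -0.00253 with 1 array left out. Apart from the filtered Hmgn5, the cause of these movements was not tested.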

Other observations

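Some lists that did not pass as a group still held genes that changed between 4 h and 24 h in control cells. In those described here genes moved both ways, except in the list of HMG proteins and linker histones. Of 44 immediate-early and serum response factor targets 3 rose and 3 fell, 5 and 4 adjusted over the list alone (camera adjusted p = 0.458). Srf itself, the transcription factor of actin and growth genes, fell by 0.77, Cnn2 by 1.25 and the focal adhesion gene Vcl by 0.43, while the antiproliferative gene Btg2 (0.79) rose. The Vcl call was lost without control 24 h replicate 2 (adjusted p = 0.0503). Of 45 integrin, laminin and matrix genes 4 rose and 2 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.985). The integrin genes Itga1 (0.77), Itgb3 (0.46) and Itga3 (0.43) rose, and Zyx (-0.49), a focal adhesion protein, fell.

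Of 45 axon guidance genes 2 rose and 1 fell, 7 and 3 adjusted over the list alone (camera adjusted p = 0.213). The semaphorin genes Sema6d (0.53) and Sema4f (0.52) rose, the semaphorin receptor gene Plxna1 (-0.30) fell, with -0.14 in a second probe set, and the guidance ligand gene Slit2 (0.29) did not pass. With 1 array left out the Sema4f call was lost in 7 of 9 fits, all but those without control 4 h replicate 2 or 3 (adjusted p up to 0.143). The Plxna1 call was lost in 6, all but these and that without Hmgn5 siRNA replicate 3 (up to 0.105). Of 31 neurotrophin and cytokine signalling genes 3 rose and 1 fell, 3 and 2 adjusted over the list alone (camera adjusted p = 0.356). Ngfr (0.65), the growth factor gene Nrg1 (0.45) and the receptor gene Igf1r (0.33) rose, and the cytokine receptor subunit gene Il6st (-0.33) fell. The Ngfr call was lost without any 1 of the 24 h control arrays (adjusted p up to 0.0712). The Nrg1 and Il6st calls were lost without control 4 h replicate 3 or control 24 h replicate 1, and without control 24 h replicate 3 for Nrg1 and 2 for Il6st (up to 0.0744 and 0.0727). The Igf1r call was lost in all fits but those without control 4 h replicate 2 or Hmgn5 siRNA replicate 2 or 3 (up to 0.103). Of 29 glycolysis and hypoxia-inducible genes 4 fell and 1 rose, 4 and 2 adjusted over the list alone. Ndrg1 (-0.34, and 0.06 in a second probe set) and the glycolytic enzyme genes Pgk1 (-0.37) and Tpi1 (-0.27) fell, and the prolyl hydroxylase subunit gene P4ha2 (0.52) rose. Without control 24 h replicate 2 the calls of all 4 were lost, and without control 24 h replicate 1 those of Pgk1, Tpi1 and P4ha2 (adjusted p up to 0.0539 for Ndrg1, 0.0641 for Pgk1, 0.0847 for Tpi1 and 0.126 for P4ha2). Tpi1 and P4ha2 were also lost without control 24 h replicate 3 and control 4 h replicate 3, Tpi1 without control 4 h replicate 1 and P4ha2 without any 1 of the knockdown arrays. That list was not called (camera adjusted p = 0.361), but it was without control 4 h replicate 2 (adjusted p = 0.00342). Among 12 HMG proteins and linker histones H1f10 (-0.46) fell, over all genes and adjusted over the list alone, and Hmgn3 (-0.12) and Hmgb1 (-0.13) did not pass (camera adjusted p = 0.449).

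The following genes were singled out after their values were seen. Capn6 had a knockdown difference of 1.02 and a time difference of -1.18, Cacna1i, a T-type calcium channel, -0.92 and 0.94, and Prkg1, a cGMP-dependent kinase, 0.38 and -0.72. At knockdown their adjusted p-values were 0.0629, 0.208 and 0.182, and all 3 genes passed over time. Both differences use the same 24 h controls with opposite sign, so genes picked for large values tend to be opposed without any effect. Nrp2, a semaphorin receptor, was 0.50 higher at knockdown (adjusted p = 0.108). With array weights Capn6, Nrp2 and Prkg1 passed at knockdown, at adjusted p 0.0285, 0.0393 and 0.0484.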
